A study of Homo sapiens with 4 samples.

How the data were processed

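H3K9me2 was profiled by CUT&RUN in K562 cells, in 2 libraries with a guide against HPRT (control) and 2 with a guide against CUX1 (knockout). Groups and replicate numbers came from the sample titles. The deposited peak names carry tags that the labels do not explain, "sub" with a number in control replicate 1 only and "cux1kd" in both knockout libraries. Whether the reads of that control were treated differently, and whether the cells are better called a knockdown, is not given in the sources used here, and "knockout" follows the labels. Per the labels' protocols, permeabilised cells were bound to beads and incubated with an antibody against H3K9me2, a protein A/G nuclease fusion released the DNA, and libraries were amplified by PCR.

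Per the submitters' processing notes, the tools were BWA 0.7.17, SAMtools 1.16.1, MACS2 2.1.0 and deepTools 3.5.1, and the genome build was hg19. Their settings, the use of a background library and the read depth were not given in the sources used here. The authors deposited 1 list of broad peaks per library, so peaks were called per library and not on pooled reads. The deposited positions were checked against chromosome lengths (GenomeInfoDb 1.38.1), and 0 chromosomes had a peak past the hg19 end while 14 had one past the hg38 end. Coordinates are hg19 and counted from 1.

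Beside its position, each deposited peak carries a score, which was 10 times the −log10 p cut to a whole number. The deposited fold (a ratio of enrichment over the caller's local background) and the −log10 of p and of q are the authors' values for each peak. They were used here only to describe, rank or filter peaks. Limits on p or q common to all lists filter on values that depend on each library's depth, so such limits do not equalise depth. The number of deposited peaks was 250000 in each list, sorted by −log10 p. The serial numbers in the peak names ran to 430436 and 386156 in the controls and to 448404 and 381380 in the knockouts, so the lists held 58.1%, 64.7%, 55.8% and 65.6% of the numbers. The numbers rose with position in 100% of neighbouring pairs on a chromosome in each list. They were read as numbering all peaks called, which the sources used here do not state. The median −log10 q was 0.0139, 0.0322, 0.0450 and 0.0469 in the same order, and 14, 310, 6 and 458 peaks reached q of 0.05. Most listed peaks were thus weak by the caller's own measure. The smallest gap between peaks was close to 4 times the smallest width in each library (1452, 1477, 1056 and 1360 bp), so the caller ran with a different smallest width and gap in each.

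Covered length was the number of bases on chromosomes 1 to 22 and X under at least 1 peak. Peaks on the mitochondrial genome and on Y were left out of covered length, sharing, windows and chromosome parts. Group means were compared by a two-sided exact permutation test, for which 2 libraries against 2 give 0.333 at the least. Sharing was measured by the Jaccard index of covered bases and by the share of peaks overlapping by 1 bp or over at least 50% of both peaks. The percent of each 100-kb window under peaks was tested with limma 3.58.1 (R 4.3.3, eBayes with a trend, Benjamini-Hochberg threshold 0.05) in windows with a mean of at least 1%. Windows of 1 Mb were tested in the same way. Neighbouring windows are not independent.

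Chromosome parts were the stretches on each side of the longest peak-free stretch of at least 2000000 bp, kept where they spanned at least 5000000 bp, which gave 41 parts. Log2 of the percent covered, relative to all parts of the library, was tested with limma without a trend. This test, the limit on p common to all lists, the filling of gaps up to 2000 bp, width divided by the smallest width, the windows without chromosomes 20 and X, the count by serial number, the alternatives for 1-Mb windows and the settings combined with quantile normalization were chosen after the data were seen. So were the ratio between the sides of a chromosome, the mitochondrial values, and the segments and steps described last. The groups, the other tests and the other alternatives were fixed before the data were examined. The windows named were, by a rule set then, the 5 per direction with the largest mean change past the threshold and with groups that did not overlap, or otherwise the 8 with the smallest unadjusted p, stated not to have passed. The 1-Mb windows and chromosome arms named were chosen after their values were seen.

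The fits were tested on simulated data with known changes, whose sizes for 100-kb windows were raised after smaller ones were rarely recovered. In 27554 windows of 100 kb, changes of 40 points were recovered in 56.0% of cases and changes of 20 points in 9.00%, with 2 false calls. In 2830 windows of 1 Mb, changes of 20 points were recovered in 50.0% and changes of 10 points in 9.00%, with 1 false call. At both window sizes the changes were placed only in more densely covered windows, so this recovery need not hold in sparsely covered ones. Windows were simulated independently and without a genome-wide difference, so the false calls need not carry over to the data. In the 41 parts, a log2 change of -1.00 was recovered in 95.5%, with 0.24 false calls per simulated set. All parts were simulated with 1 common spread, while the SE in the data ran from 0.0446 on the high-coordinate arm of chromosome 4 to 0.42 on that of X. The recovery in parts therefore need not hold for those with a wide spread. A change smaller than these could pass unseen, and in such a part so could a larger one.

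Gene bodies, promoters, genomic features and gene lists were planned and were not analysed here, since no annotation of hg19 was used. Values at CUX1 and HPRT1 themselves are therefore not given, and the peak lists do not show whether either gene was disrupted. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.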

Results

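The data were genome-wide maps of H3K9me2, the dimethyl mark on lysine 9 of histone H3 that covers broad, mostly silent stretches of chromatin, in K562 cells. K562 is an established human myeloid leukemia cell line. The mark was mapped by CUT&RUN, in which an antibody tethers a nuclease to the marked nucleosomes and the released DNA is sequenced. The 2 control libraries came from cells given a guide RNA against HPRT, and the 2 knockout libraries from cells given a guide against CUX1, a homeodomain transcription factor encoded on the long arm of chromosome 7. Each library was represented by its own list of broad peaks on hg19, and each list held 250000 peaks. Read depth was not given in the sources used here, so the precision that depth gives each library was unknown. The labels number the libraries but do not say that they came from separate cultures, so the tests measure the spread between libraries, which may be technical.

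The comparison asked whether H3K9me2 was reduced in cells without CUX1, the question named in the title of the series. In the lists as deposited, peaks on chromosomes 1 to 22 and X covered 686 ± 10.1 Mb in control cells and 504 ± 114 Mb in CUX1 knockout cells (SD, n = 2 each), a difference of -26.5%. The controls covered 693 and 679 Mb, and the knockouts 423 Mb (replicate 1) and 585 Mb (replicate 2). Both knockout libraries lay below both controls, and the two-sided exact permutation p was 0.333, the smallest that 2 libraries against 2 allow. As a share of these chromosomes, peaks covered 22.6% ± 0.331 in control and 16.6% ± 3.76 in knockout cells (SD, n = 2 each).

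The number of peaks could not carry a difference, since every list ended at 250000 peaks. The lists ended at different strengths, with a lowest −log10 p of 1.25 and 1.27 in the controls and 1.49 and 1.35 in the knockouts. When 1 limit of 1.49 was set for all lists, a choice made after the data were seen, covered length was 282 and 307 Mb in the controls and 423 and 346 Mb in the knockouts. With that limit the knockout mean was higher by 90.7 Mb. A common limit on −log10 q was set at the median of all peaks (0.0335). This is far weaker than a q of 0.05, which at most 458 peaks of a list reached. With it the knockout mean was higher by 111 Mb. The groups then overlapped, with 141 and 339 Mb in the controls and 295 and 408 Mb in the knockouts (exact permutation p = 0.667). The direction of the genome-wide difference in means thus followed the limit at which the lists were read.

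**Figure D1:**
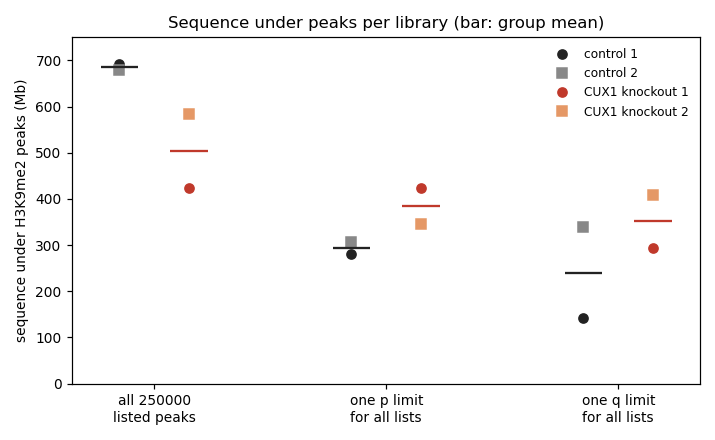
Sequence under H3K9me2 peaks (Mb, vertical axis) for each control and CUX1 knockout library, for the whole lists, for peaks past 1 limit of −log10 p and for peaks past 1 limit of −log10 q. Points are libraries and bars are group means; the knockout mean was 504 Mb against 686 Mb for the whole lists and 385 against 294 Mb with 1 limit of p.

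H3K9me2 peaks were narrower in the knockout libraries. The median peak width was 2335 and 2275 bp in the controls, 1324 bp in knockout replicate 1 and 1900 bp in knockout replicate 2, a difference between group means of -30.1% (exact permutation p = 0.333, n = 2 each). Peaks of at least 5000 bp held 207 ± 9.34 Mb in control and 85.4 ± 63.1 Mb in knockout cells, a difference of -58.7% (SD, n = 2 each). The knockout value was 40.8 Mb in replicate 1 and 130 Mb in replicate 2. Peaks of at least 2000 bp held 565 ± 12.3 and 350 ± 133 Mb, a difference of -38.0%, with 256 Mb in knockout replicate 1 and 444 Mb in knockout replicate 2. The smallest peak in a list was 362 and 369 bp wide in the controls and 263 and 339 bp in the knockouts, so the caller's own lower limit also differed between libraries, and width divided by that limit differed by -15.7%.

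Libraries of 1 group were on average about as alike as libraries of different groups. The Jaccard index, the bases shared by a pair of libraries over the bases covered in either, was 0.230 for the controls and 0.157 for the knockouts, and between 0.160 and 0.221 for the 4 pairs of a control with a knockout. Random placement of the same lengths would give between 0.0880 and 0.127. Both controls and neither knockout covered 115 Mb, and both knockouts and neither control covered 44.0 Mb. Pairing the libraries across groups gave 55.7 and 93.0 Mb for 1 split and 90.1 and 52.9 Mb for the other, and 33.7 Mb was covered in all 4 libraries. At equal covered length the group-specific amounts were 52.3 Mb for the controls and 47.7 Mb for the knockouts, and with 1 limit of −log10 p they were 27.9 and 48.3 Mb.

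Chromosome 20 stood out among the chromosomes. Peaks covered 15.6% ± 0.302 of it in control and 6.29% ± 0.0449 in knockout cells (SD, n = 2 each), a ratio of 0.403. Chromosome X followed, with 6.47% ± 1.15 and 3.44% ± 0.760 (SD, n = 2 each) and a ratio of 0.532. The knockout mean was lower on all 23 chromosomes in the whole lists, with overlapping groups on chromosomes 13, 14 and 22, and chromosome 7 had the next lowest ratio, 0.667. With 1 limit of −log10 p, and likewise with 1 limit of −log10 q, chromosome 20 was the only chromosome of the 23 on which the knockout mean was lower. On chromosome 20 the former gave 6.18% ± 0.673 against 4.95% ± 1.95 and the latter 4.80% ± 2.95 against 3.03% ± 0.0324 (control against knockout, SD, n = 2 each), differences of the whole chromosome within the spread of 1 group.

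By coverage, the difference on chromosome 20 lay mostly on its long arm. From 29519749 to 62887644, peaks covered 24.01% ± 0.162 in control and 6.86% ± 0.456 in knockout cells (SD, n = 2 each). On the short arm, from 61802 to 26183928, the values were 7.06% ± 0.935 and 6.43% ± 0.691. On the long arm of chromosome X, from 61920830 to 154929189, coverage was 6.39% ± 1.24 in control and 1.62% ± 0.458 in knockout cells, against 7.37% ± 1.14 and 6.87% ± 1.35 on the short arm, from 2699575 to 58458541. The division into 41 chromosome parts was chosen after the data were seen. Relative to all parts of the same library, the long arm of chromosome 20 fell by 1.35 on the log2 scale (SE 0.13, adjusted p = 0.0402 over the 41 parts, limma), the only part past the threshold. With the limit on −log10 q its log2 difference was -1.79 (limma, adjusted p = 0.00635), and with the limit on −log10 p it was -1.35 and did not pass (adjusted p = 0.0575). The long arm of X had a log2 difference of -1.53 (SE 0.42) that did not pass (adjusted p = 0.224). Its relative log2 values were -1.75 and -2.12 in control replicates 1 and 2, and -2.94 and -3.99 in knockout replicates 1 and 2. Replicate 1 lay above replicate 2 in both groups on this and all other parts of the 8 with a control mean under 12%. On denser parts the order varied. The fit without a replicate block counts such a shift as spread. Without control replicate 1 or control replicate 2 the adjusted p for chromosome 20 was 0.274 or 0.299, with log2 differences of -1.37 and -1.33.

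The serial numbers in the peak names, read as numbering all peaks called, gave a further count that included peaks past the end of the lists; this reading is not stated in the sources used here. By that count the long arm of chromosome 20 held 153 ± 5.13 peaks per Mb in control and 84.8 ± 9.83 in knockout cells (SD, n = 2 each), and fell by 0.88 on the log2 scale relative to all parts (limma, adjusted p = 0.000179). The long arm of X held 102 ± 27.8 and 31.3 ± 12.3 peaks per Mb and fell by 1.76 (limma, adjusted p = 0.000504). The short arms were also lower by this count, from 111 to 86.8 peaks per Mb on chromosome 20 (log2 difference -0.36, limma adjusted p = 0.303) and from 111 to 89.6 on X (-0.33, adjusted p = 0.427). The other parts with a control mean coverage under 12% were lower too. Examples are 91.0 to 72.4 on the low-coordinate arm of chromosome 17 (-0.34) and 104 to 86.7 on chromosome 13 (-0.26). Over the 12 settings run, the log2 difference ranged from -1.79 to -0.88 on the long arm of chromosome 20 (adjusted p from 0.000179 to 0.299) and from -2.05 to -1.004 on that of X (adjusted p from 0.000504 to 0.890).

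The ratio between the sides of a chromosome within a library compares regions read from the same list. It was chosen after the data were seen, and chromosomes 20 and X were set apart from the others for their low values. On chromosome 20 the long arm was covered 3.10 and 3.77 times as densely as the short arm in the controls, and 0.945 and 1.21 times in the knockouts. On X the ratio was 0.888 and 0.840 in the controls and 0.249 and 0.220 in the knockouts. The change in the log2 ratio was -1.68 on chromosome 20 and -1.88 on X, while over the other 16 chromosomes with both sides measured it lay between -0.40, on chromosome 9, and 0.31 (SD 0.18). By serial number the change was smaller on chromosome 20, -0.52, and was -1.44 on X, with the others between -0.22 and 0.39.

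**Figure D2:**
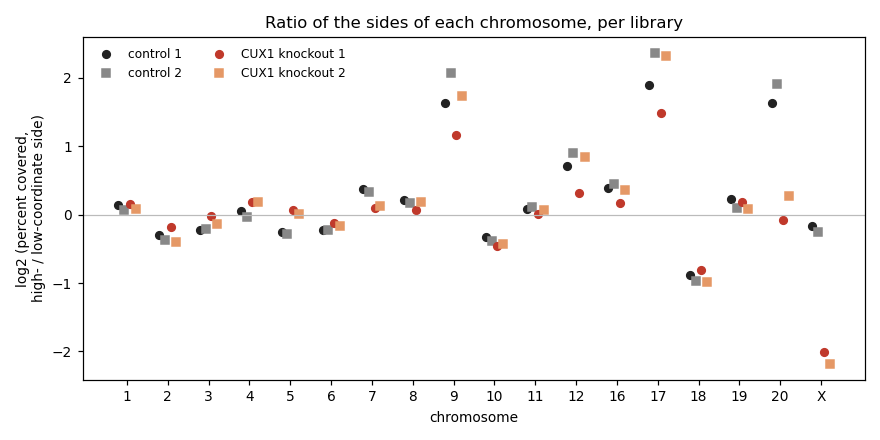
Log2 of the percent covered on the high-coordinate side over that on the low-coordinate side (vertical axis, log2 scale) for the 18 chromosomes with both sides measured (horizontal axis). Points are the 4 libraries; both knockout libraries lay apart from both controls on chromosome 20, with a mean change of -1.68, and on X, with -1.88.

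In windows of 1 Mb, a scale that was an alternative to windows of 100 kb and is described first because more windows passed, 122 of 2830 windows passed (limma, Benjamini-Hochberg adjusted p under 0.05). Coverage fell in 120 and rose in 2. The long arm of chromosome 20 held 33 of the falls among its 34 windows, and the long arm of X 68 among 89, which left 19 elsewhere, including 8 on the long arm of chromosome 7 and 6 on the low-coordinate arm of chromosome 5. After quantile normalization, which sets the distributions of the 4 libraries equal, 39 windows passed and 37 of them fell, 18 on the long arm of chromosome 20 and 18 on that of X. With 1 limit of −log10 p, 17 windows passed and all 17 rose, and with 1 limit of −log10 q limma called 0, with 110 at an unadjusted p under 0.05. Leaving out 1 library gave 94 (control 1), 110 (control 2), 355 (knockout 1) and 1747 windows (knockout 2). In the same order, falls numbered 20, 19, 33 and 33 of the 34 windows on the long arm of 20, 67, 70, 31 and 51 of the 89 on that of X, and 6, 21, 290 and 1647 of the 2707 elsewhere. At equal covered length 12 falls were on that of 20 and 0 on that of X.

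The 2 windows of 1 Mb in which coverage rose were on chromosome 9 and on X. On chromosome 9, from 13000001 to 14000000, peaks covered 6.99% and 3.64% in the controls and 22.8% and 22.9% in the knockouts (limma, adjusted p = 0.00014, and 0.0294 after quantile normalization). On X, from 84000001 to 85000000, they covered 3.35% and 5.00% in the controls and 13.0% and 9.90% in the knockouts (limma, adjusted p = 0.0107, and 0.0808 after quantile normalization). Without control replicate 1 or control replicate 2 neither passed. The differences were then 19.2 and 15.8 points on chromosome 9, against 17.5 with all libraries (adjusted p = 0.273 and 0.781), and 6.43 and 8.09 points on X, against 7.26 (adjusted p = 0.821 and 0.107). Without knockout replicate 1 the window on X did not pass (5.72 points, adjusted p = 0.111). The window on X lay inside the long arm, whose coverage as a whole was lower in the knockouts. From 81 to 98 Mb on that arm, a stretch that holds the window, coverage was 2.94% ± 0.751 in control and 3.83% ± 0.0326 in knockout cells (SD, n = 2 each).

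**Figure D3:**
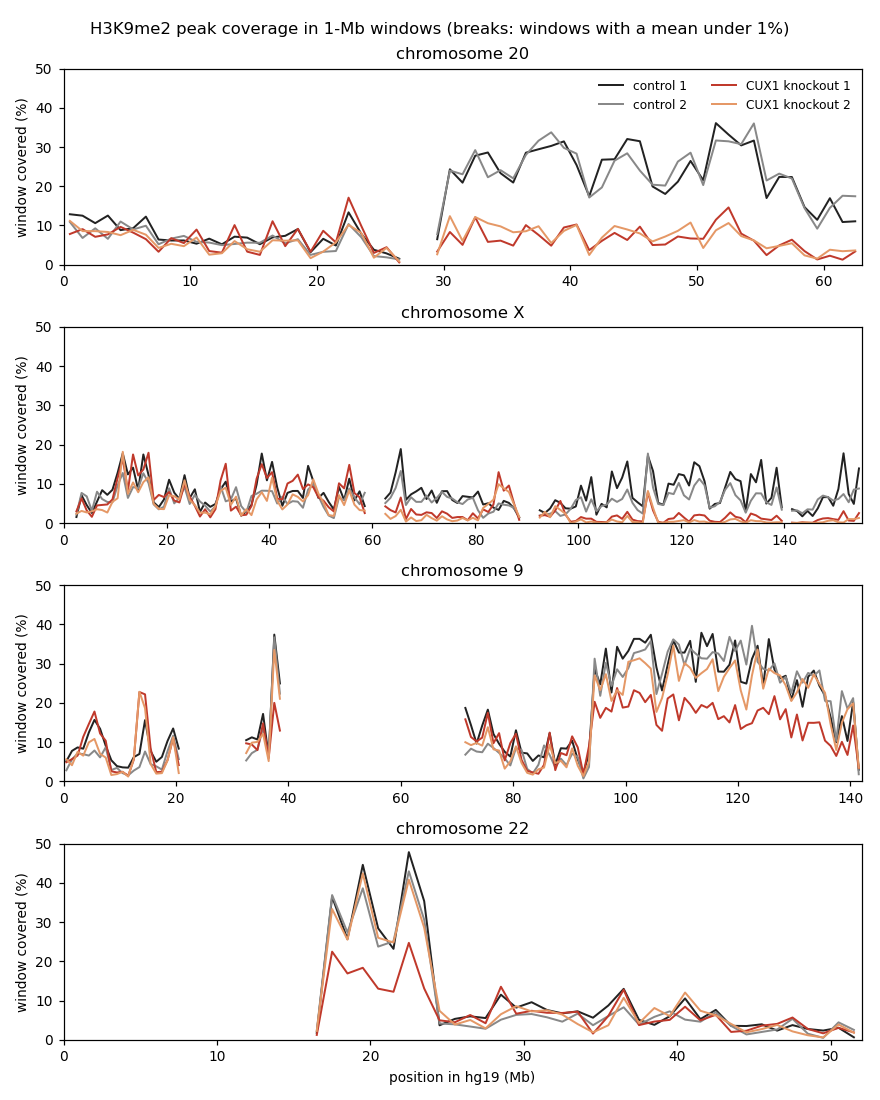
Percent of each 1-Mb window covered by H3K9me2 peaks (vertical axis) along chromosomes 20, X, 9 and 22 (horizontal axis, position in Mb), 1 line per library. Both knockout lines ran below both control lines in all 34 windows of the long arm of chromosome 20 and in 77 of 89 windows of that of X. Elsewhere this share varied, from 3 of 23 windows on the low-coordinate arm of chromosome 17 to 98 of 98 on the long arm of 7. On chromosomes 9 and 22 the libraries shared abrupt steps at 94 and 24 Mb.

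In windows of 100 kb, the scale set before the data were examined, 27 of 27554 windows passed, and coverage fell in all 27, by between -17.6 and -41.6 percentage points. Of these, 14 were on the long arm of chromosome 20, 4 on chromosome 7, 3 on the long arm of X and 6 elsewhere. The largest fall was on chromosome 20 from 44100001 to 44200000, where coverage went from 54.8% and 40.8% in the controls to 5.91% and 6.46% in the knockouts, a difference of -41.6 points (SE 7.84, limma adjusted p = 0.0030). On chromosome 20 the windows starting at 38100001 and 51300001 fell from a mean of 40.5% to 2.00% and from 40.5% to 4.58% (limma, adjusted p = 0.0108 and 0.0252). On chromosome 7 the windows starting at 110100001 and 71500001 fell from 47.6% to 9.73% and from 48.7% to 12.3% (limma, adjusted p = 0.0143 and 0.0252). None of these 5 windows passed with a common limit, where their differences were -16.7 to -5.69 points (−log10 q) and -15.3 to -10.001 points (−log10 p).

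No window of 100 kb rose past the threshold. The 8 with the smallest unadjusted p included 3 on chromosome 9, starting at 13000001, 13400001 and 14000001, with means of 5.34% against 27.6%, 2.31% against 21.3% and 9.16% against 35.0% (control against knockout, limma adjusted p = 0.115, 0.0820 and 0.0989). On X, the windows starting at 84100001 and 84300001 had 0.813% against 12.04% and 1.75% against 18.7% (adjusted p = 0.0982 and 0.0788). The others were on chromosome 3, starting at 81500001 and 67500001, with 1.59% against 19.8% and 0.254% against 9.86%, and on the short arm of chromosome 20, starting at 10400001, with 1.61% against 14.5% (adjusted p = 0.0730, 0.102 and 0.101). The window on chromosome 3 starting at 67500001 rested on 1 library, with 18.9% in knockout 1 and 0.788% in knockout 2, and without knockout 1 its difference was 0.534 points.

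At an unadjusted p under 0.05 the 100-kb windows numbered 4129. Both knockout libraries lay below both controls in 43.3% of windows and above both in 4.98%, where chance gives 16.7% each way. After quantile normalization these shares were 18.98% and 18.93%, and limma called 0 windows, with 2206 at an unadjusted p under 0.05. The 5 windows named above then had differences of -35.4 to -29.1 points, against -41.6 to -35.9 before (limma, adjusted p from 0.477 to 0.504). With 1 library left out after quantile normalization, a choice made after the data were seen, the calls ranged from 2 without knockout 1 to 300 without knockout 2. Of these 300, 195 rose, while falls outnumbered rises in the other 3 settings. Without that normalization, leaving out 1 library gave 315 windows (control 1), 654 (control 2), 9 (knockout 1) and 2312 (knockout 2), so the count rested on which libraries entered.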

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

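All tests that weigh an explanation here were chosen after the results were seen. Peaks on the mitochondrial genome, which were left out of covered length and windows, covered 11601 bp in knockout replicate 1 and 13336 bp in knockout replicate 2, above the 11256 and 10603 bp of the controls (exact permutation p = 0.333, the smallest that 2 libraries against 2 allow).

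The first pattern is the lower covered length of the knockout libraries. That the lists end at different p values may account for its direction, since with 1 limit for all lists the knockout mean was higher by 90.7 Mb. This limit was the end of the list of knockout replicate 1, which it left whole, and p values depend on a depth that is unknown. A difference in the caller's smallest width and gap cannot be told apart from narrower domains, because width in units of the smallest width still differed by -15.7% and need not scale with it. A loss of H3K9me2 with CUX1 stays open, and lists cut to 1 length per library hold no measure of the total mark.

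The second pattern is the lower coverage of the long arms of chromosomes 20 and X in both knockout libraries. A difference in list length, depth or p limit was weighed by the knockout to control ratio in the whole lists. It was 0.286 on 20q against 0.619 to 0.887 on the 32 other dense chromosome parts. On Xq it was 0.254, against 0.838 to 0.978 on the 7 other sparse parts. Both arms were picked for their low values, so their place below the other parts is no test. At equal covered length the log2 differences were still -1.52 on 20q and -1.34 on Xq, but neither passed (limma, adjusted p = 0.229 and 0.437). Equal length thus did not remove the differences. Depth stays unknown, and this cause is not excluded. A single deviant library is argued against on 20q by the log2 change of -1.18 that remained, as the weaker of both, when 1 knockout library was left out. A difference in DNA copy number between the cell populations cannot be told apart from other causes: both knockouts lay below both controls in 100% of 1-Mb windows on 20q and 86.5% on Xq, but the arms were picked for their low values and 4 other parts reached at least 90%, among them 47 of 47 windows on the low-coordinate arm of chromosome 5 and 98 of 98 on the long arm of 7. Among the other parts this share ran down to 3 of 23 windows on the low-coordinate arm of chromosome 17. It was 91 of 109 on the high-coordinate arm of chromosome 6 and 89 of 104 on that of chromosome 1. The share on Xq was thus not apart from those of dense parts. It was above those of the 7 other sparse parts, the highest of which was 12 of 29 on the low-coordinate arm of chromosome 9. Since Xq was picked for its low values, this is no test. An effect of CUX1 loss on the mark over 20q and Xq is untested and would need DNA copy number from the same cells.

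The third pattern is the presence, on some chromosomes, of large plateaus of coverage shared by the libraries, described among the other observations. That peak calls follow the amount of DNA as well as the mark is a candidate explanation, not tested on nuclear DNA. In 4 of 4 lists the peak with the lowest p was on mitochondrial DNA, which is present in many copies and has no histones. DNA without the mark could thus be called. This does not measure how much of any nuclear plateau comes from copy number. No biological explanation was tested.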

How the results depend on the processing

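The limit on p common to all lists, gaps filled to 2000 bp, width in units of the smallest width, windows without chromosomes 20 and X, settings combined with quantile normalization, and every setting for 1-Mb windows and chromosome parts were chosen after the result was seen. Covered length (-182 Mb) became 111 Mb with the q limit, where the groups overlapped, and 90.7 Mb with the p limit. Group-specific sequence (control minus knockout, 71.2 Mb) became -31.3 Mb with the q limit, -20.5 Mb with the p limit and 4.66 Mb at equal length. Leaving out 1 library gave -262 to -101 Mb, -42.6 to -17.6% for width and 21 to 23 lower chromosomes. Chromosomes with a lower knockout mean, 23, became 1 with either limit and 10 at equal length. The difference in peak number (-1) became 73342 with the q limit and -29054 for peaks of at least 1000 bp. The difference in median peak width (-30.1%) was -23.7% with the q limit and -27.7% with the p limit. In units of the smallest width it was -15.7%. Sharing kept within the spread of pairs in all settings. The causes were not tested.

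The 27 windows of 100 kb became 0 with the q limit, with the p limit, at equal length, after quantile normalization, without a trend and with 10-kb windows (1017, 2778, 1694, 2206, 4321 and 9773 at an unadjusted p under 0.05, limma). They became 9 for peaks of at least 1000 bp, 17 with gaps filled to 2000 bp, 1 without chromosomes 20 and X, 225 on the arcsine scale (220 fell), 122 at 1 Mb and 9 to 2312 with 1 library left out (lowest without knockout 1, highest without knockout 2). The lone library of a group was then assumed to vary like the others. Filling gaps to 1000 bp could move nothing, since the smallest gap in any list was 1056 bp. The 122 windows of 1 Mb became 39 after quantile normalization, 0 with the q limit (110 at an unadjusted p under 0.05), 35 at equal length (24 fell), 17 with the p limit (all rose) and 94 to 1747 with 1 library left out. The long arm of chromosome 20 (-1.35) had -1.52 at equal length, -1.35 with the p limit and -1.35 with gaps filled (adjusted p = 0.229, 0.0575 and 0.0597, limma), and -1.51 to -1.18 with 1 library left out. That of X (-1.53) had -1.76 by serial number (adjusted p = 0.000504, limma) and -2.05 to -1.004 with 1 library left out. The 5 named falls passed in 33 of 55 values and in 0 of 5 with the q limit (-16.7 to -5.69 points), with the p limit (-15.3 to -10.001), at equal length (-30.8 to -13.1) and after quantile normalization (-35.4 to -29.1). On chromosome 20 the window at 44100001 ranged from -48.6 to -6.83 points. The 8 named rises passed in 10 of 88, and that on chromosome 3 at 67500001 ranged from 0.534 to 18.7 points.

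With the replicate number as a block, limma called 173 windows of 100 kb (169 fell) and 231 of 1 Mb (222 fell, 116 of them outside the long arms of 20 and X), and 6 of 100 kb after quantile normalization (5 fell). The long arm of X (-1.53) and, upward, the low-coordinate arm of 9 (0.45) then passed (adjusted p = 0.0436 for both). Their SE fell (0.42 to 0.188 and 0.286 to 0.0625), while on some parts it rose. In windows, deviations of same-numbered libraries correlated at 0.0562 (0.0653 after quantile normalization). On all 8 sparse parts replicate 1 lay above replicate 2 in both groups, with no test of pairing. The planned gene and feature analyses were not run, for want of an hg19 annotation. Unknown depth limits every level compared between lists.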

Other observations

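The segments and steps described here, and their tests, were all chosen after the profiles had been seen. On some chromosomes H3K9me2 coverage formed plateaus many megabases long with abrupt ends. A search for places where the means of the 8 windows of 1 Mb on either side differed by a factor of at least 2 in every library, and which by design kept only steps shared by all 4, found 7 on 7 of the 23 chromosomes, at 48 Mb on chromosome 3, 94 Mb on 9, 21 Mb on 12, 90 Mb on 13, 41 Mb on 14, 40 Mb on 18 and 24 Mb on 22. On chromosome 3, coverage from 1 to 47 Mb was 40.1% ± 0.768 in control and 26.9% ± 8.42 in knockout cells, and from 48 to 90 Mb 6.51% ± 1.43 and 6.78% ± 1.39 (SD, n = 2 each). On chromosome 22 it was 33.3% ± 1.64 and 24.4% ± 10.2 from 17 to 24 Mb, and 5.26% ± 1.04 and 5.31% ± 0.185 beyond. On chromosome 18 it was 37.1% ± 0.844 and 24.2% ± 6.74 from 19 to 39 Mb, and 6.37% ± 1.75 and 5.74% ± 1.20 from 40 to 78 Mb. On chromosome 9 from 21 to 31 Mb peaks were nearly absent from all libraries, with 0.101% ± 0.113 in control and 0.164% ± 0.175 in knockout cells.

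Ratios of knockout to control differed between sparse and dense parts of the genome, which was not tested. Among the 8 chromosome parts with a control mean under 12%, the 7 other than the long arm of X had knockout to control ratios between 0.838 and 0.978. Among the 33 denser parts, the 32 other than the long arm of chromosome 20 had ratios between 0.619 and 0.887. In the knockout libraries the long arm of chromosome 20 was at 6.86% ± 0.456, beside 6.43% ± 0.691 on the short arm of the same chromosome.

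On the long arm of X, coverage was 7.16% ± 1.11 in control and 1.83% ± 0.857 in knockout cells between 62 and 81 Mb, and 7.14% ± 1.42 and 0.894% ± 0.452 beyond 98 Mb (means, SD, n = 2 each, no test of these segments). Between 81 and 98 Mb it was 2.94% ± 0.751 in control and 3.83% ± 0.0326 in knockout cells. On chromosome 9 from 13 to 15 Mb coverage was 8.47% ± 4.01 in control and 21.6% ± 1.22 in knockout cells, while in the 10 Mb before it was 6.53% ± 2.30 and 6.70% ± 1.93.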
